A study of Mus musculus with 12 samples.

How the data were processed

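The values analysed were the deposited counts per gene symbol, 12 tables of 23282 lines each. Per the submitters' processing notes reads were aligned with TopHat to mm10 before the counts were deposited. The version of TopHat, the counting program, the gene annotation and the strand setting are not given in the sources used here. Per the labels' protocols RNA was extracted with Trizol and 1.3 µg of total RNA per sample went into libraries made with the NEBNext Ultra II Directional kit. Symbols on more than one line (35 symbols, 79 lines) were summed, which left 23238 symbols, of which 22197 matched GENCODE M21, the source of the coordinates. Among the symbols that did not match were Irg1, Ear12 and Cyr61, which are named below.

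Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with a fit of all 12 samples, the default expression filter and TMM scaling. The filter kept 16484 genes and removed 6754. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and the standard error is the absolute log2 change divided by the square root of F. CPM use the scaled library sizes, and values after ± are SD over 3 libraries. The 51 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated from the data. Each list's members were also adjusted over the list alone. Groups, comparisons, lists, settings and the rule for naming genes were written before the data were examined. The removal of Rn45s and the haemoglobin genes, the added lists and the tests said to be chosen later came after it.

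By the naming rule each comparison with unirradiated lung gives the 10 highest and 10 lowest log2 changes among called genes with a mean of at least 5 CPM and all 3 libraries on the same side of all 3 controls. Comparisons between times give 5 in each direction. Not every gene that the rule selects is printed below. Immunoglobulin and T cell receptor segments, haemoglobin genes and unnamed loci were left out. Up to 4 members per list with the lowest p over all groups were added, with Cdkn1a, Mdm2, Sftpc, Ager, Xist and Ddx3y. Genes named outside this rule, such as list members that went against their list (Fas, Rrm2b, Perp, Xpc, Cd36, Cd163, Clec9a, Cxcl12, Il18, Itgax and Apln) and the genes of the closing parts, were chosen after the values were seen. Alternatives were median-of-ratios scaling, library size alone, no filter, a filter of 10 counts in all samples of a group, a replicate block, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, and each library left out. In a self-test 200 genes were changed in simulated counts of 15962 genes modelled on 8 d and unirradiated lung. Of the genes changed 1.5-fold 17.9% were recovered, of those changed 2-fold 76.1%, of those changed 4-fold 93.9%, and 3 of 128 calls were false.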

Results

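RNA was sequenced from mouse lung in 12 samples that fall into 4 groups of 3. One group received no irradiation, and the others were taken 8, 11 and 14 days after irradiation. Per the series description the irradiated samples came only from irradiated areas of the lung. Dose, strain, age and the region from which the control tissue was taken are not given in the sources used here. The comparisons ask how the lung transcriptome differed from unirradiated lung at each time and how it changed between the times. The libraries held 26164354 to 27765751 counts without irradiation, 20792968 to 22660158 at 8 d, 19624554 to 24502421 at 11 d and 22615862 to 25524425 at 14 d. Between 18204 and 19288 genes were detected per library, and 16484 genes entered the tests. The labels number the replicates but do not say that they are separate animals, so p-values measure the spread between these samples, which may be technical.

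Identity and composition of the libraries were checked before any comparison. Ddx3y, a Y-linked gene, lay between 91.2 and 112 CPM (counts scaled by library size) in the group means, and Xist, which is expressed from the inactive X chromosome, between 0.456 and 0.755 CPM. Rn45s, a ribosomal RNA precursor, took 2.22% ± 0.622 of counts without irradiation (SD, n = 3), 3.38% ± 0.607 at 8 d, 4.49% ± 1.55 at 11 d and 2.78% ± 0.647 at 14 d. Its highest share was 6.27%, in 11 d replicate 2. Haemoglobin genes took 1.35% ± 0.405 of counts without irradiation, 1.51% ± 0.318 at 8 d, 0.933% ± 0.302 at 11 d and 0.381% ± 0.122 at 14 d. The first principal component carried 54.6% of the variance and placed the unirradiated libraries between -79.46 and -70.77 and the irradiated ones between -5.98 and 49.74. On this axis 11 d replicate 1 lay at 48.2, among the 14 d libraries, while 11 d replicates 2 and 3 lay at 20.88 and 23.16.

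**Figure D1:**
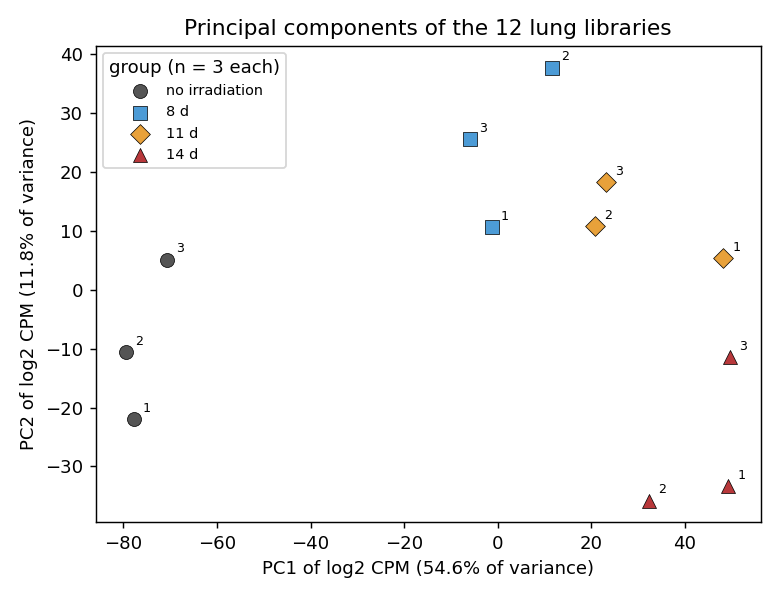
Each point is a library (3 per group, replicate number beside it), plotted by its score on the first 2 principal components of log2 CPM, whose axes carry 54.6% and 11.8% of the variance. Unirradiated libraries have first-component scores of -70.77 or lower, 8 d libraries lie between -5.98 and 11.68, and 11 d and 14 d libraries lie at 20.88 or above.

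Counts of changed genes rose from 8 d to 11 d and were close at 11 d and 14 d. At 8 d, 3891 genes differed from unirradiated lung at an adjusted p below 0.05 (edgeR quasi-likelihood test, n = 3 per group), 2139 higher and 1752 lower. At 11 d there were 6132, of which 3194 were higher, and at 14 d 6408, of which 3292 were higher. Scaling by library size alone gave 2438 rises and 1352 falls at 8 d (64.3% rises in place of 55%) and 3010 and 3139 at 11 d, where the majority turned. Changes of at least 2-fold made up 1147 of the rises and 451 of the falls at 8 d, and 1845 and 1298 at 14 d. Between time points the counts were 353 from 8 d to 11 d, 296 from 11 d to 14 d and 2536 from 8 d to 14 d. A joint test of any difference among the 4 groups called 6465 genes.

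**Figure D2:**
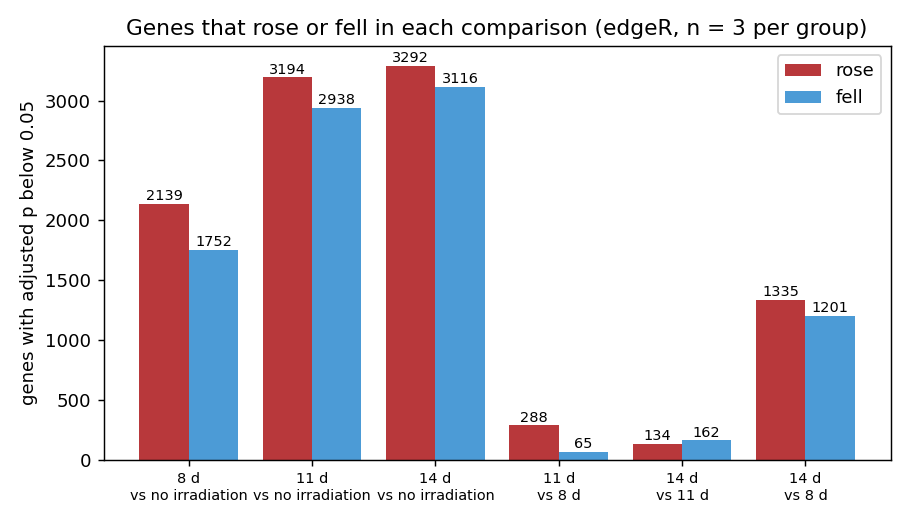
Bars give the number of genes with an adjusted p below 0.05 in edgeR (y axis) that rose or fell in each of the 6 comparisons (x axis), with n = 3 per group and no error bars because each bar is a count. The comparison of 14 d with no irradiation has 3292 rises and 3116 falls, and that of 14 d with 11 d has 134 and 162.

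At 8 d genes of the p53 response, interferon response and leukocyte recruitment rose. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases (mm10 chromosome 17, 29090976 to 29100727, plus strand), rose from 24.8 ± 4.86 to 287 ± 6.22 CPM (SD, n = 3), a log2 change of 3.53 (SE 0.18, adjusted p = 8.5e-08). Ccl2, which attracts monocytes (chromosome 11, 82035571 to 82037453), rose from 0.43 ± 0.151 to 24.7 ± 9.5 CPM, a log2 change of 5.83 (SE 0.39, adjusted p = 6.7e-07). Tek, the endothelial angiopoietin receptor (chromosome 4, 94739289 to 94874976), fell from 518 ± 23 to 142 ± 14.2 CPM, a log2 change of -1.87 (SE 0.16, adjusted p = 5e-06). Of the 30 p53 target genes 24 rose and 2 fell (25 and 2 adjusted over the list alone), with a median log2 change of 1.42. The list was shifted with a preset correlation (camera adjusted p = 1.67e-36), and its adjusted p = 0.0062 with an estimated correlation was the lowest of the 51 lists. Gdf15, a stress-induced growth factor of the TGF-beta family, rose by 5.76 (SE 0.34), Eda2r, a receptor of the TNF receptor family, by 4.32 (SE 0.33), Psrc1 by 3.92 (SE 0.16) and Mdm2, the ubiquitin ligase that degrades p53, by 1.46 (SE 0.11), all log2. The 2 that fell were Fas and Rrm2b. The largest rises of named genes were in Irg1, the macrophage enzyme that makes itaconate, with a log2 change of 6.94 (SE 0.64) over only 6 counts in the unirradiated libraries together, and the acute-phase gene Saa3 with 6.48 (SE 0.57). The carboxylesterase gene Ces2e rose by 4.50 (SE 0.33).

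Interferon and antigen-presentation genes rose together at 8 d. All but 1 of 24 type I interferon-stimulated genes rose (23 adjusted over the list alone, median log2 change 1.48; camera adjusted p = 1.03e-28, and adjusted p = 0.0596 with an estimated correlation). Among them Cxcl10, a chemokine for activated T cells, rose by 4.96 (SE 0.32), Mx1, an antiviral GTPase, by 3.65 (SE 0.29), Zbp1, a sensor of Z-form nucleic acid, by 3.03 (SE 0.25) and Ifit1 by 2.07 (SE 0.20). Of 23 interferon-gamma response genes 17 rose (18 adjusted over the list alone, adjusted p = 0.119 with an estimated correlation), led by Cxcl9 with 4.16 (SE 0.34). All 10 genes of MHC class II presentation rose, with all 10 also passing adjusted over the list alone and an adjusted p = 0.0764 with an estimated correlation. H2-Ab1, which encodes a class II beta chain, rose by 1.51 (SE 0.19). Of 35 cytokine and chemokine genes 24 rose and 3 fell (26 and 3 adjusted over the list alone, adjusted p = 0.0556 with an estimated correlation). The 3 lower ones were Ccl21a, a lymphatic chemokine with near-identical genomic copies whose count is therefore uncertain, Cxcl12 and Il18.

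Markers of several leukocyte types were higher at 8 d, which these counts do not separate from entry of cells, local expansion or altered expression. Neutrophil markers rose in 6 of 11 (10 adjusted over the list alone, adjusted p = 0.207 with an estimated correlation). All 13 markers of NK and cytotoxic cells rose (13 adjusted over the list alone, median 2.18; adjusted p = 0.0556 with an estimated correlation), among them Xcl1 by 4.39 (SE 0.42) and the activating receptor Klrk1 by 2.67 (SE 0.26). T cell markers rose in 18 of 21 (18 adjusted over the list alone, adjusted p = 0.0698 with an estimated correlation), including the kinase Lck by 2.04 (SE 0.19). Dendritic cell markers rose in 11 of 13 and fell in 1, Clec9a (11 and 1 adjusted over the list alone, adjusted p = 0.0556 with an estimated correlation). Monocyte markers rose in 10 of 12, including Ccr2, the receptor for Ccl2, by 2.57 (SE 0.28), and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.0675 with an estimated correlation). B cell markers rose in 11 of 14 and fell in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.207 with an estimated correlation). Alveolar macrophage markers went the other way, with 9 of 14 lower and 2 higher (9 and 2 adjusted over the list alone, median -1.01; adjusted p = 0.0556 with an estimated correlation). Fabp1, a fatty acid-binding protein, fell from 17.4 ± 0.266 to 2.93 ± 0.635 CPM (log2 change -2.57, SE 0.28), while the scavenger receptor Marco and the integrin Itgax rose.

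Of 27 markers of blood vessel endothelium 19 fell and 1, the angiogenic peptide gene Apln, rose (22 and 1 adjusted over the list alone, median -0.92; camera adjusted p = 1.83e-16, and adjusted p = 0.0675 with an estimated correlation). Ednrb, an endothelin receptor, fell by 2.29 on the log2 scale (SE 0.25), Tmem100 by 1.96 (SE 0.25) and Calcrl, the receptor subunit for adrenomedullin, by 1.34 (SE 0.14). Thbd, which encodes the anticoagulant thrombomodulin, changed by -1.83 (SE 0.23). Alveolar type 1 cell markers fell in 7 of 14 (10 adjusted over the list alone, adjusted p = 0.149 with an estimated correlation), for example Clic5 from 1071 to 466 CPM (adjusted p = 3.4e-05). Alveolar type 2 cell markers showed no shift (camera adjusted p = 0.59), with 2 of 18 higher and 3 lower (2 and 3 adjusted over the list alone), and Sftpc, the surfactant protein C gene, had a log2 change of -0.41 (SE 0.20) that did not pass. Markers of transitional alveolar epithelium rose in 9 of 16 and fell in none (10 adjusted over the list alone, adjusted p = 0.0596 with an estimated correlation). This list shares Lgals3 with the lipid-associated macrophage markers, so its rise here and later is not assigned to epithelium alone. Lcn2, an iron-siderophore binding protein, went from 106 ± 16.5 to 963 ± 174 CPM (log2 change 3.18, SE 0.18). Alveolar fibroblast markers fell in 6 of 11 (6 adjusted over the list alone, adjusted p = 0.247 with an estimated correlation) and mesothelial markers in 6 of 8 (8 adjusted over the list alone, adjusted p = 0.207 with an estimated correlation). Matrix genes rose in 17 of 35 and fell in 1 (18 and 2 adjusted over the list alone, adjusted p = 0.207 with an estimated correlation), including tenascin C, Tnc, by 2.64 (SE 0.20) and fibronectin, Fn1, from 269 ± 67.4 to 760 ± 200 CPM. Mitosis genes rose in 15 of 22 (20 adjusted over the list alone, adjusted p = 0.173 with an estimated correlation). Clock output genes fell in 7 of 10 (7 adjusted over the list alone, adjusted p = 0.173 with an estimated correlation). Glucocorticoid response genes fell in 6 of 10 and rose in 1 (6 and 2 adjusted over the list alone, median -0.73). That list was called lower at 8 d (camera adjusted p = 0.008, and adjusted p = 0.31 with an estimated correlation). It was not called at 11 d or 14 d (camera adjusted p = 0.95 and 0.803). Immediate early genes, which also respond to tissue handling, rose in 6 of 14 and fell in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.304 with an estimated correlation). Skeletal and cardiac muscle markers rose in 4 of 12 and 1 of 12 (5 and 0 adjusted over the list alone), without a call for either list (camera adjusted p = 0.0594 and 0.897). Without unirradiated replicate 1 the test called 2593 genes at 8 d in place of 3891.

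**Figure D3:**
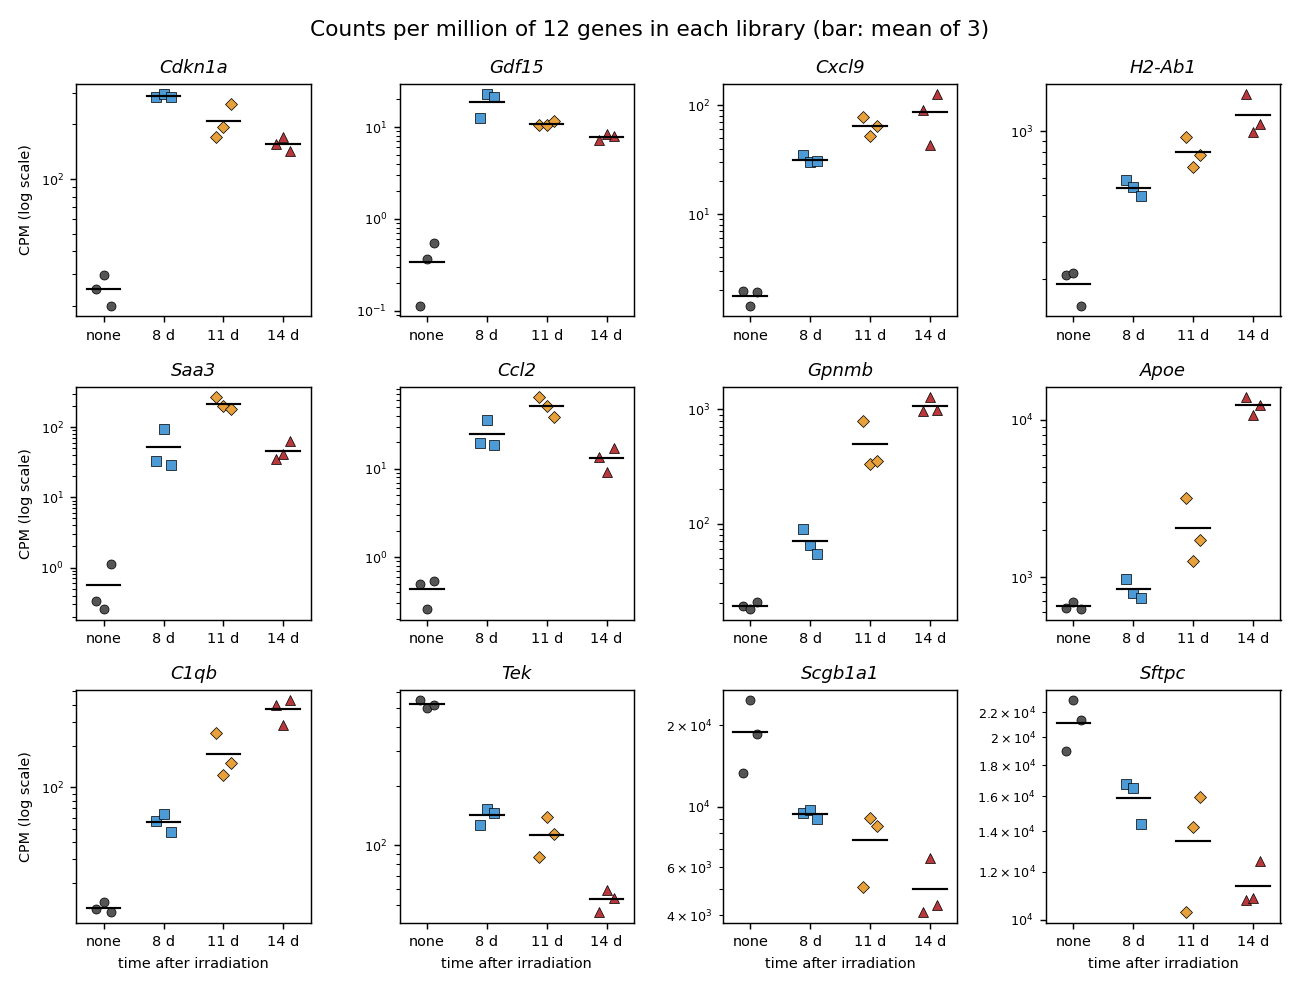
CPM on a log axis (y) of 12 genes in each library, by time after irradiation (x; none is unirradiated lung); points are the 3 libraries of a group and bars their means, with no error bars. Cdkn1a mean CPM is 24.8 without irradiation and 287, 208 and 156 at 8, 11 and 14 d, while Apoe is 653 without irradiation and 12311 at 14 d.

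At 11 d inflammatory, macrophage and cell-cycle genes stood above unirradiated lung. Saa3 (chromosome 7, 46711998 to 46715700, minus strand) rose from 0.573 ± 0.476 to 214 ± 45 CPM, a log2 change of 8.52 (SE 0.60, adjusted p = 4.5e-07), and Ccl2 reached 51.7 ± 13.2 CPM, a log2 change of 6.89 (SE 0.40, adjusted p = 1.9e-07). Msr1, a macrophage scavenger receptor, rose from 2.76 ± 1.24 to 107 ± 33.7 CPM, a log2 change of 5.27 (SE 0.34, adjusted p = 3e-07). All 22 mitosis genes rose (22 adjusted over the list alone, median 1.53; camera adjusted p = 4.53e-14, and adjusted p = 0.0879 with an estimated correlation). Top2a, the topoisomerase of dividing cells, rose by 1.83 (SE 0.18) and Cdk1, the mitotic kinase, by 2.16 (SE 0.21). DNA replication genes rose in 17 of 22 and fell in 1 (17 and 1 adjusted over the list alone, adjusted p = 0.149 with an estimated correlation). Of the p53 targets 22 rose and 2 fell (22 and 3 adjusted over the list alone, adjusted p = 0.0583 with an estimated correlation), and Cdkn1a stood at 208 ± 46.3 CPM. All 24 type I interferon-stimulated genes rose (24 adjusted over the list alone, median 1.89; adjusted p = 0.0858 with an estimated correlation). Cytokine and chemokine genes rose in 28 of 35 and fell in 3 (28 and 4 adjusted over the list alone, median 3.23; adjusted p = 0.0583 with an estimated correlation), with Ccl3 at 5.27 (SE 0.34) and Il12b at 4.66 (SE 0.31). Inflammasome and necroptosis genes rose in 13 of 13 (13 adjusted over the list alone, adjusted p = 0.125 with an estimated correlation), for example the adaptor Pycard by 2.35 (SE 0.29).

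Macrophage lists at 11 d rose in part and fell in part. Lipid-associated macrophage markers rose in 11 of 14 and fell in 1, Cd36 (12 and 1 adjusted over the list alone, median 2.11; camera adjusted p = 8.95e-13, and adjusted p = 0.0879 with an estimated correlation). Gpnmb, a lysosomal glycoprotein of activated macrophages (chromosome 6, 49036546 to 49070929, plus strand), rose by 4.70 (SE 0.33) and Spp1, which encodes osteopontin, by 4.38 (SE 0.38). Interstitial macrophage markers rose in 9 of 12 and fell in 1, Cd163 (9 and 1 adjusted over the list alone, adjusted p = 0.0917 with an estimated correlation), with the complement gene C1qa at 3.64 (SE 0.23). Alveolar macrophage markers fell in 8 of 14 and rose in 4 (8 and 4 adjusted over the list alone, adjusted p = 0.125 with an estimated correlation). T cell markers rose in 20 of 21 (20 adjusted over the list alone, adjusted p = 0.0858 with an estimated correlation). Neutrophil markers rose in 8 of 11 (8 adjusted over the list alone, adjusted p = 0.217 with an estimated correlation). The list of B cell markers was not called (camera adjusted p = 0.117), with 5 of 14 higher and 1 lower (5 and 1 adjusted over the list alone).

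Endothelial, alveolar fibroblast, smooth muscle and mesothelial markers fell at 11 d. Activated myofibroblast markers, with 5 of 14 higher and 1 lower, and adventitial fibroblast markers, with 1 of 9 higher and 5 lower, were not called as lists (5 and 2, and 2 and 6, adjusted over the list alone, camera adjusted p = 0.112 and 0.143). For the myofibroblast list the median of -0.21 and the mean of 0.60 differ in sign. Endothelial markers fell in 24 of 27 and rose in 1, Apln (24 and 1 adjusted over the list alone, median -1.24; adjusted p = 0.0595 with an estimated correlation), and Tek stood at 113 ± 25.5 CPM, a log2 change of -2.19 (SE 0.17). All 8 mesothelial markers fell (8 adjusted over the list alone, median -1.72; adjusted p = 0.1015 with an estimated correlation). Alveolar fibroblast markers fell in 9 of 11 (10 adjusted over the list alone) and smooth muscle and pericyte markers in 11 of 17 with 1 higher (12 and 1 adjusted over the list alone), each with adjusted p = 0.125 with an estimated correlation. The growth factor-binding gene Igfbp5 changed by -2.47 (SE 0.33), the microsomal monooxygenase Fmo1 by -2.42 (SE 0.23) and the long non-coding RNA Fendrr by -2.46 (SE 0.38). Alveolar type 1 markers fell in 10 of 14 and rose in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.125 with an estimated correlation), while transitional epithelium markers rose in 12 of 16 (12 adjusted over the list alone, adjusted p = 0.0583 with an estimated correlation) and Lcn2 reached 1591 ± 166 CPM. The eosinophil-associated ribonuclease gene Ear1 changed by -2.48 (SE 0.19), but it belongs to a family of near-identical copies and its count is uncertain. Leaving out any 1 of the 6 libraries compared gave between 4426 and 5453 changed genes.

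At 14 d genes of phagocytic, lipid-handling macrophages rose. Apoe, which encodes apolipoprotein E (chromosome 7, 19696109 to 19699188, minus strand), rose from 653 ± 34.2 to 12311 ± 1584 CPM, a log2 change of 4.24 (SE 0.30, adjusted p = 3.1e-07). Gpnmb rose from 19.1 ± 1.36 to 1080 ± 173 CPM, a log2 change of 5.82 (SE 0.35, adjusted p = 1.4e-07), and Trem2, a lipid-sensing receptor of macrophages, from 2.26 ± 0.159 to 101 ± 11.4 CPM, a log2 change of 5.48 (SE 0.34, adjusted p = 1.4e-07). Tek was down to 53.1 ± 6.94 CPM, a log2 change of -3.29 (SE 0.17, adjusted p = 1.1e-07). Lipid-associated macrophage markers rose in 12 of 14 and fell in 1, Cd36 (12 and 1 adjusted over the list alone, median 2.74; camera adjusted p = 1.57e-14, and adjusted p = 0.0844 with an estimated correlation). Interstitial macrophage markers rose in 9 of 12 and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.0844 with an estimated correlation). The complement list held 7 higher and 3 lower of 18 (7 and 3 adjusted over the list alone), with a median of -0.05, a mean of 0.94 and a camera call upward that was lost at adjusted p = 0.132 with an estimated correlation. The 3 C1q chain genes rose by 4.59 (C1qa, SE 0.23), 4.81 (C1qb, SE 0.27) and 4.63 (C1qc, SE 0.28). The cysteine protease gene Ctss rose by 4.30 (SE 0.32), the metalloelastase gene Mmp12 by 4.32 (SE 0.25) and Fn1 by 2.72 (SE 0.27). Proteases and their inhibitors rose in 15 of 22 and fell in 2 (15 and 2 adjusted over the list alone, adjusted p = 0.057 with an estimated correlation).

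T cell, mast cell and cell-cycle genes also stood above unirradiated lung at 14 d, while the B cell and plasma cell lists were not called (camera adjusted p = 0.277 and 0.11). B cell markers rose in 3 of 14 and fell in 1, and plasma cell markers rose in 4 of 9 (3 and 1, and 5 and 1, adjusted over the list alone). Jchain, a plasma cell marker, held 561 counts in the unirradiated libraries together, 2488 at 11 d and 10376 at 14 d. The missing call of the list therefore does not show that plasma cell genes were unchanged. T cell markers rose in 19 of 21 (19 adjusted over the list alone, adjusted p = 0.103 with an estimated correlation), with Ctla4, an inhibitory receptor of T cells, at 5.05 (SE 0.38). Mast cell and basophil markers rose in 8 of 9 and fell in 1, the transcription factor gene Gata2 (8 and 1 adjusted over the list alone, adjusted p = 0.103 with an estimated correlation). Cpa3, a mast cell carboxypeptidase, rose from 0.537 ± 0.349 to 20 ± 7.79 CPM, a log2 change of 5.20 (SE 0.47). MHC class II genes rose in 10 of 10 (10 adjusted over the list alone, median 2.10; adjusted p = 0.0844 with an estimated correlation), and Cd74, the invariant chain, went from 703 ± 111 to 3279 ± 720 CPM. Mitosis genes rose in 22 of 22 (22 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation). Of the p53 targets 21 rose and 4 fell, namely Fas, Perp, Xpc and Rrm2b (21 and 4 adjusted over the list alone, adjusted p = 0.0844 with an estimated correlation). NK and cytotoxic cell markers rose in 11 of 13 (11 adjusted over the list alone, adjusted p = 0.235 with an estimated correlation). The neutrophil list was not called (camera adjusted p = 0.166), with 4 of 11 higher (4 adjusted over the list alone).

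Markers of blood vessels, alveolar fibroblasts, smooth muscle, mesothelium and club cells fell at 14 d. Adventitial fibroblast markers fell in 4 of 9 and rose in 1 (4 and 1 adjusted over the list alone, adjusted p = 0.284 with an estimated correlation) and lymphatic endothelium markers fell in 4 of 7 (5 adjusted over the list alone, adjusted p = 0.105 with an estimated correlation). Activated myofibroblast markers rose in 7 of 14 and fell in 3 (7 and 3 adjusted over the list alone, adjusted p = 0.171 with an estimated correlation). Collagen and matrix genes rose in 16 of 35 and fell in 3 (16 and 3 adjusted over the list alone, adjusted p = 0.327 with an estimated correlation). Endothelial markers fell in 26 of 27, with Apln at 0.36 and not passing (26 adjusted over the list alone, median -2.02; camera adjusted p = 9.21e-32, and adjusted p = 0.057 with an estimated correlation). Hpgd, which inactivates prostaglandins, fell from 1150 ± 123 to 99.2 ± 25.5 CPM, a log2 change of -3.54 (SE 0.24), and Tmem100 from 356 ± 44.1 to 27.9 ± 6.32 CPM, a log2 change of -3.67 (SE 0.27). All 8 mesothelial markers fell (8 adjusted over the list alone, median -2.40; adjusted p = 0.0999 with an estimated correlation), for example Upk3b from 82 ± 10.1 to 6.66 ± 3.4 CPM, a log2 change of -3.62 (SE 0.47). Smooth muscle and pericyte markers fell in 14 of 17 and rose in 1 (14 and 1 adjusted over the list alone, adjusted p = 0.132 with an estimated correlation), and alveolar fibroblast markers fell in 9 of 11 (9 adjusted over the list alone, adjusted p = 0.138 with an estimated correlation). Alveolar type 1 markers fell in 11 of 14 (11 adjusted over the list alone, adjusted p = 0.105 with an estimated correlation). Alveolar type 2 markers were not called as a list (camera adjusted p = 0.256), with 6 of 18 lower and 2 higher (6 and 2 adjusted over the list alone). Sftpc changed by -0.89 (SE 0.20, adjusted p = 0.0024). Club cell markers fell in 6 of 13 (6 adjusted over the list alone, adjusted p = 0.332 with an estimated correlation), and Scgb1a1, the club cell secretoglobin (chromosome 19, 9083636 to 9087958), fell from 18862 ± 5690 to 4984 ± 1311 CPM, a log2 change of -1.92 (SE 0.28). Ciliated cell markers were not called as a list (camera adjusted p = 0.147), with 2 of 16 lower (1 adjusted over the list alone). Cholesterol synthesis genes fell in 12 of 19 and rose in 2 (13 and 2 adjusted over the list alone, adjusted p = 0.427 with an estimated correlation), and clock output genes fell in 9 of 10 and rose in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.132 with an estimated correlation). Red cell genes fell in 8 of 10 (9 adjusted over the list alone, adjusted p = 0.348 with an estimated correlation), among them haemoglobin genes that share reads with near-identical copies and are uncertain one by one. Leaving out any 1 of the 6 libraries compared gave between 5184 and 6060 changed genes.

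**Figure D4:**
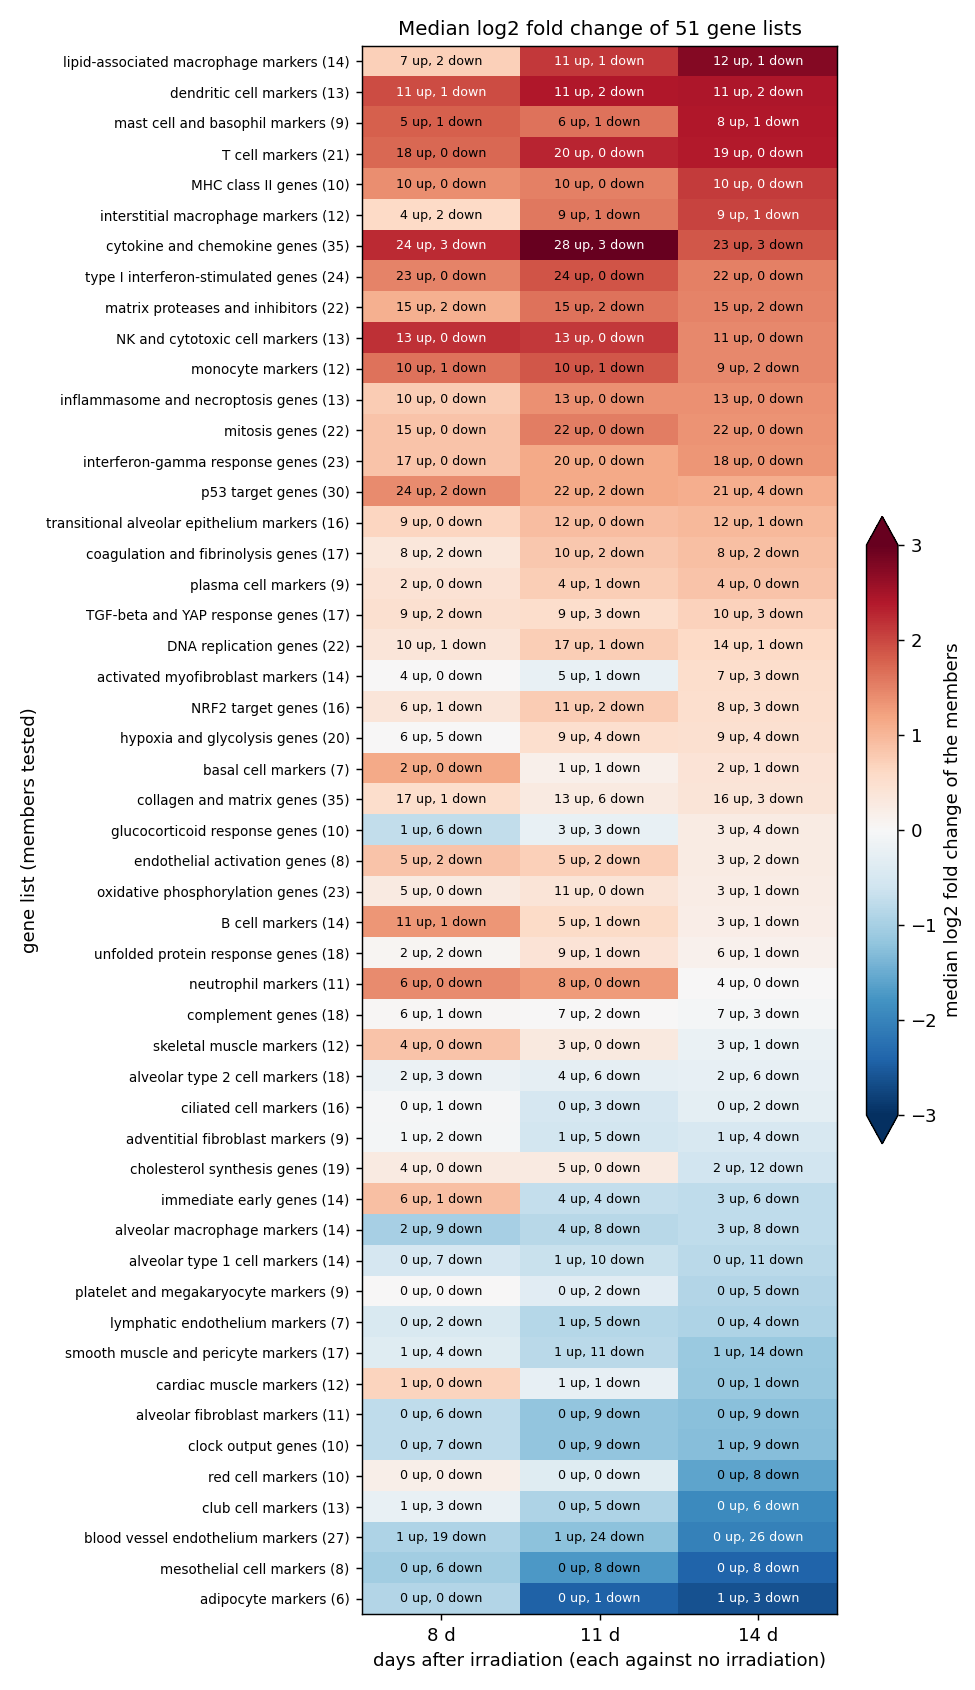
Colour gives the median log2 fold change of the tested members of 51 gene lists (y axis, number tested in brackets) at 8, 11 and 14 d against unirradiated lung (x axis), n = 3 per group, and the text in each cell gives how many members rose or fell at an adjusted p below 0.05 in edgeR. Colours end at -3 and 3; lipid-associated macrophage markers have medians of 0.70, 2.11 and 2.74 and blood vessel endothelium markers -0.92, -1.24 and -2.02, and the hypoxia, platelet and ciliated cell medians, which lie near 0 at 8 d, change sign there under other scalings.

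From 8 d to 11 d macrophage genes rose further. Gpnmb rose from 69.9 ± 18.2 to 495 ± 264 CPM, a log2 change of 2.83 (SE 0.30, adjusted p = 0.0016), and Spp1 from 254 ± 89 to 1400 ± 509 CPM, a log2 change of 2.46 (SE 0.34, adjusted p = 0.011). Cxcl13, a B cell chemokine, rose by 2.46 (SE 0.36). Immediate early genes, which also respond to tissue handling, fell, with the transcription factor genes Egr1 at -2.67 (SE 0.62, adjusted p = 0.043) and Nr4a1 at -2.47 (SE 0.49, adjusted p = 0.021) and the matricellular gene Cyr61 at -1.56 (SE 0.34, adjusted p = 0.03). Lipid-associated macrophage markers rose in 10 of 14 (13 adjusted over the list alone, median 1.22; adjusted p = 0.0789 with an estimated correlation) and interstitial ones in 7 of 12 (9 adjusted over the list alone, adjusted p = 0.0789 with an estimated correlation). Mitosis genes rose in 2 of 22, or 14 adjusted over the list alone, with an adjusted p = 0.115 with an estimated correlation. Immediate early genes fell in 4 of 14 (10 adjusted over the list alone, adjusted p = 0.123 with an estimated correlation), and no endothelial marker passed over all genes (3 fell adjusted over the list alone, adjusted p = 0.21 with an estimated correlation). In all, 288 genes rose and 65 fell. Scaling by library size alone moved the median log2 change of all genes to -0.102 and gave 186 rises and 121 falls, so rises were 60.6% of calls in place of 81.6%. Single libraries decided this count, which was 2 without 8 d replicate 3, 207 without 8 d replicate 1, 545 without 8 d replicate 2 and 54 without 11 d replicate 1. Without 8 d replicate 3 Gpnmb alone of the 10 genes named for their size in this comparison kept its call.

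From 11 d to 14 d Apoe rose again while acute inflammatory genes fell. Apoe went from 2054 ± 1009 to 12311 ± 1584 CPM, a log2 change of 2.58 (SE 0.28, adjusted p = 8.3e-04). Irg1 fell from 37.2 ± 12.2 to 4.4 ± 1.7 CPM, a log2 change of -3.09 (SE 0.39, adjusted p = 0.0033), and Clec4e, a receptor for mycobacterial and damage-associated glycolipids, from 83.9 ± 29.6 to 14 ± 2.84 CPM, a log2 change of -2.58 (SE 0.34, adjusted p = 0.0037). Ear2 and Ear12 rose by 1.66 and 1.65 (SE 0.16 each), returning to near their unirradiated level with the uncertainty of near-identical copies. Cytokine and chemokine genes fell in 9 of 35 (16 fell and 1 rose adjusted over the list alone, adjusted p = 0.168 with an estimated correlation), and type I interferon-stimulated genes fell in 6 of 24 (11 adjusted over the list alone, adjusted p = 0.298 with an estimated correlation). Endothelial markers fell in 12 of 27 (22 adjusted over the list alone, median -0.79; camera adjusted p = 4.63e-27, and adjusted p = 0.166 with an estimated correlation), with Tek at -1.09 (SE 0.16, adjusted p = 0.0075). Cholesterol synthesis genes fell in 9 of 19 (16 adjusted over the list alone, adjusted p = 0.168 with an estimated correlation), led by Idi1 at -1.48 (SE 0.21) and Fdps at -1.37 (SE 0.18), enzymes of isoprenoid synthesis. Red cell genes fell in 3 of 10 (7 adjusted over the list alone, adjusted p = 0.298 with an estimated correlation). Neutrophil markers fell in 1 of 11 (5 adjusted over the list alone, camera adjusted p = 7.89e-04, and adjusted p = 0.35 with an estimated correlation). In all, 134 genes rose and 162 fell, and scaling by library size alone gave 161 and 132 (54.9% rises in place of 45.3%). This count was 13 without 14 d replicate 1, 102 without 14 d replicate 2, 24 without 11 d replicate 2, 52 without 11 d replicate 3 and 681 without 11 d replicate 1, the library that lay among those of 14 d on the first principal component. Of the 10 genes named for their size in this comparison, Apoe, Ear2, Ear12, Irg1 and Clec4e kept their call under every setting run.

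Between 8 d and 14 d 1335 genes rose and 1201 fell, a majority that turned to 1116 and 1457 with scaling by library size alone (43.4% rises in place of 52.6%). Gpnmb rose by 3.95 (SE 0.32, adjusted p = 2.8e-05), Apoe by 3.88 (SE 0.30, adjusted p = 2.8e-05) and Ctss by 3.45 (SE 0.31, adjusted p = 3.2e-05). Fabp1 fell by 3.19 on the log2 scale (SE 0.38), Nr4a1 by 2.93 (SE 0.50) and Upk3b by 2.56 (SE 0.45). Lipid-associated macrophage markers rose in 13 of 14 (13 adjusted over the list alone) and interstitial ones in 8 of 12 (8 adjusted over the list alone), while endothelial markers fell in 19 of 27 (25 adjusted over the list alone). These 3 lists were called with both a preset and an estimated correlation (adjusted p = 0.0475 each with the estimate). Cdkn1a was lower at 14 d than at 8 d by 0.88 (SE 0.17, adjusted p = 0.0027), and p53 targets fell in 11 of 30 (11 adjusted over the list alone, adjusted p = 0.169 with an estimated correlation). All 8 mesothelial markers fell (8 adjusted over the list alone, adjusted p = 0.0979 with an estimated correlation), as did 14 of 19 cholesterol synthesis genes (17 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation) and 8 of 14 B cell markers, with 1 higher (10 and 1 adjusted over the list alone, adjusted p = 0.329 with an estimated correlation). The count of changed genes was 1392 without 14 d replicate 1 and 1600 without 8 d replicate 3. Egr1, named for its size, lost its call without 14 d replicate 1, where its log2 change was -2.58.

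The 3 comparisons with unirradiated lung shared many calls. Rises at all 3 times were found for 1636 genes and falls for 1400, of 8020 genes called at any time. Between 8 d and 11 d 1870 rises and 1552 falls were shared and no gene was called in opposite directions, where independent lists of these sizes would share 414.5 and 312.3. Between 11 d and 14 d 2511 rises and 2322 falls were shared (637.9 and 555.4 for independent lists), and between 8 d and 14 d 1706 and 1468 (427.2 and 331.2), with 17 genes in opposite directions. The comparisons use the same control libraries, which alone correlate their values. In 20 simulations of unchanged groups against shared controls the mean correlation of log2 changes across genes was 0.477 to 0.487. Observed were 0.893, 0.914 and 0.837 for 8 and 11 d, 11 and 14 d, and 8 and 14 d. The simulations gave no shared call, but no gene was changed in them, so this is no baseline for the counts of shared calls. The covariances were 0.646, 0.886 and 0.663, against 0.046, 0.045 and 0.046 simulated. The 3 control libraries cannot be split with 2 in each part, so part of the excess of shared calls over independent lists may come from the shared controls.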

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

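Of the tests below, the comparison of endothelial with alveolar type 2 markers was chosen only after the fall of endothelial markers was seen. Blood vessel endothelium markers had a median log2 change of -1.12 between 8 d and 14 d, while lipid-associated macrophage markers had 1.60 and interstitial macrophage markers 1.52. Entry of other cells into the tissue would dilute all resident cells alike. At 14 d, however, the endothelial median lay below that of alveolar type 2 markers. The difference was -1.775 (bootstrap of list members -2.17 to -1.35, permutation of list members p = 1.00e-05, the smallest possible). Both treat the genes of a list as independent and do not measure the spread between libraries. The call of the endothelial list at 14 d was lost with an estimated correlation (camera adjusted p = 0.057). After correction for gene length and GC content the difference was -1.735. Length or GC bias is therefore unlikely to be the whole cause. The difference depends on the list compared, and of those given here alveolar type 2 markers fell least by their median. Members of that list were uneven, with 6 of 18 lower and 2 higher at 14 d. From unirradiated lung to 14 d summed counts went from 379124 to 168864 for Sftpb and from 132162 to 55440 for Slc34a2. Those of Scd1 rose from 63282 to 220763, so the median does not show that alveolar type 2 cells were spared. Medians at 14 d were -0.24 for them, -0.81 for alveolar type 1, -1.10 for smooth muscle and pericyte and -1.26 for alveolar fibroblast markers. They were -1.92 for club cell, -2.02 for endothelial and -2.40 for mesothelial markers. Equal dilution alone does not give such unequal medians, but its share in the endothelial fall is not settled. Fewer endothelial cells or lower expression in them also remain possible explanations that these counts do not separate.

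Clock output genes fell in 7, 9 and 9 of 10 at 8, 11 and 14 d (7, 9 and 9 adjusted over the list alone), and 1 rose at 14 d (1 at 11 d and 1 at 14 d adjusted over the list alone). The list had adjusted p = 0.173, 0.111 and 0.132 with an estimated correlation. Its median at 14 d was -1.287 before and -1.241 after correction for length and GC content, so this bias is an unlikely cause. Of 5 genes set beforehand as having the opposite daily phase 3 rose at 14 d. They were Arntl by 1.76 (SE 0.28), Nfil3 by 2.27 (SE 0.18) and Clock by 0.35 (SE 0.13). Clock passed narrowly (adjusted p = 0.049), Npas2 did not pass, and Cry1 lay lower without passing (-0.51, SE 0.20, adjusted p = 0.0583). At 8 d and at 11 d only Arntl and Nfil3 rose, and at 8 d Cry1 fell by 0.61 on the log2 scale (SE 0.20, adjusted p = 0.0405). Arntl and Nfil3 rose at all 3 times, as collection at another time of day predicts, and Cry1 lay lower at all 3, unlike the rise set for it. The mark set beforehand for this explanation, a rise of at least 3 of the 5 at 14 d, was met only through Clock. With Npas2 not passing and Cry1 lower, the values at all 3 times go with this explanation only in part. The collection times are not given in the sources used here.

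Among the genes named by the rule, Idi1 and Nr4a1 were called in opposite directions at different times. Idi1, an isoprenoid enzyme, was 0.58 above unirradiated lung at 11 d and 0.90 below at 14 d, a difference of -1.48 (SE 0.21, adjusted p = 0.0065). Nr4a1, an immediate early gene, was 1.48 above at 8 d and 1.46 below at 14 d, a difference of -2.93 (SE 0.50, adjusted p = 0.0013). Its unirradiated libraries spread widely, at 19.6 ± 18.4 CPM.

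Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. In all 6 comparisons 1 split of 10, the real one, reached the real count. The highest count in another split was 0 in every comparison except 14 d against 11 d, where it was 1. For the 4 groups 1 of 100 splits reached the real 6465 genes, and the highest other gave 3431.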

How the results depend on the processing

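Counts between adjacent times depended on the method and on single libraries far more than counts against unirradiated lung. Leaving out libraries at 8 d gave 2593 (unirradiated replicate 1) to 3544 (8 d replicate 1), and DESeq2 called 4457. Between 8 d and 11 d DESeq2 called 868 genes, a fit of only the groups compared 143, and leaving out libraries gave 2 (8 d replicate 3) to 545 (8 d replicate 2). Between 11 d and 14 d DESeq2 called 827, and leaving out libraries gave 13 (14 d replicate 1) to 681 (11 d replicate 1). Between 8 d and 14 d leaving out libraries gave 1392 (14 d replicate 1) to 2548 (8 d replicate 2), and DESeq2 called 3130. With an estimated correlation 1 list was called at 8 d, 0 at 11 d, 0 at 14 d, 0 for 11 d against 8 d, 0 for 14 d against 11 d and 3 for 14 d against 8 d. With a replicate block the counts were 3704, 5921 and 6288 against unirradiated lung, 391 for 11 d against 8 d, 425 for 14 d against 11 d and 2476 for 14 d against 8 d. To look for pairing, deviations of log2 CPM from the group mean were correlated between libraries of different groups. Of 18 pairs with equal replicate numbers 5 correlated above 0.1 (range -0.353 to 0.287). A pair with unequal numbers, 8 d replicate 2 and 14 d replicate 3, reached 0.462. Yet 8 of 12 samples correlated best with a sample of their own number, so pairing was not assumed but is not excluded. Without Rn45s and the haemoglobin genes, a setting added after the data were seen, the counts were 3893, 6127 and 6399 against unirradiated lung. Of 8781 recomputed calls of named genes 8574 stayed, 207 were lost and 0 reversed. Only genes called in the main fit were recomputed. Apart from those named regardless of values, they were chosen for large changes or a low p in the same data. The share that stayed therefore does not describe calls in general, and it pools comparisons with unirradiated lung and those between times.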

Other observations

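The lists in this part and the test of airway genes were chosen only after the results were seen. Lysosomal genes rose with the macrophage markers: 8 of 27 at 8 d, 18 at 11 d and 25 at 14 d, where Ctsd, the aspartic protease cathepsin D, rose by 3.12 (SE 0.22) and Psap, the saposin precursor, by 2.84 (SE 0.23). Subunits of the vacuolar proton pump rose in 2, 11 and 12 of 15, with Atp6v0d2 at 1.83 (SE 0.17) at 14 d. Of 7 Fc receptor genes 6 rose at 14 d, including Fcgr1 by 3.77 (SE 0.32), and Fcgrt, the neonatal receptor, fell. All 9 genes of immune checkpoints rose at 14 d, with Pdcd1 at 5.19 (SE 0.44) and Cd274, its ligand, at 1.83 (SE 0.16). T cell markers rose beside them in 19 of 21 (median 2.38) and share Ctla4, so a change per cell is not separated from more T cells.

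Monooxygenase genes of the flavin and P450 families fell in 9, 10 and 9 of 13, with Cyp4b1 at -2.87 (SE 0.27) and Fmo1 at -3.47 (SE 0.24) at 14 d. The P450 gene Cyp2f2 is also a club cell marker, and club cell and endothelial markers fell at 14 d too (6 of 13 and 26 of 27), so lower expression is not separated from fewer of these cells. Genes of Notch and VEGF signalling fell in 9, 14 and 14 of 17, alongside 19, 24 and 26 of 27 blood vessel endothelium markers, a list that shares Kdr, so a change in the pathway is not separated from the fall of endothelial markers. The Notch ligand Dll4 was at -2.98 (SE 0.20), the VEGF receptor Kdr at -1.95 (SE 0.21) and Vegfa at -1.63 (SE 0.19) at 14 d. Called in opposite directions at 8 d and 14 d were 17 genes, 10 of them higher later, including the phagocytic receptors Mertk (-0.64 and 0.83, adjusted p = 2.76e-04 for the difference) and Mrc1 (-0.57 and 0.64, adjusted p = 8.85e-05).

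Club cell markers fell more than ciliated cell markers at 14 d, by a median difference of -1.621 (bootstrap of list members -2.42 to -0.59, permutation of list members p = 0.0013). Both treat the genes of a list as independent and do not measure the spread between libraries. Of the 13 club cell markers 6 fell, and the call of their list was lost with an estimated correlation (camera adjusted p = 0.332). Less airway in the tissue taken would lower both. A loss equal for both lists alone does not give such unequal medians at 14 d. Because the spread between libraries was not measured, the test does not settle whether the loss was equal. An unequal loss stays open, since the region from which the control tissue was taken is not given. At 11 d an equal loss stays open too. The ciliated list was called lower there (median -0.49, camera adjusted p = 0.0179, and adjusted p = 0.544 with an estimated correlation). The club list was not (median -0.92, camera adjusted p = 0.0901). For the fall of cholesterol synthesis genes from 11 d to 14 d a possible explanation is sterol loading of cells, which would raise LXR target genes. The test used 7 targets not named before, of which 1 rose, Abcg1 by 0.87 (SE 0.20, adjusted p = 0.0443), with a median of 0.29. The targets left out because their rise was known were Apoe, higher by 2.58 (SE 0.28), and Abca1, by 1.68 (SE 0.28, adjusted p = 0.0119), a call lost without 11 d replicate 2 (1.44), 11 d replicate 3 (1.59) or 14 d replicate 1 (1.60). Sterol loading stays undecided.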
